A study of Mus musculus with 32 samples.

How the data were processed

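Uncapped poly(A) RNA from 5 ug of total RNA per sample was ligated to an adapter and sequenced as short tags, per the labels. The samples were brain, heart, kidney and liver of 6 male mice and spleen of 8 other male mice, 32 libraries in all, grouped by organ and by genotype as the sample titles state. Per the labels, the authors used the genome build GRCm39, featureCounts and Subread 2.0.3 for counting, and DESeq2, whose version and model are not stated.

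The deposited tables, 1 per organ, hold the authors' comparison and no values per library. Their mean per gene is a signal in normalized counts, averaged by the authors over all libraries of the organ after division by size factors. The deposited fold change and its standard error are on the log2 scale, as the authors' DESeq2 fit gives them, and were not shrunken. The deposited Wald statistic is a score that equals the fold change divided by its standard error, which was checked in every row. The deposited p-value and adjusted p-value are the authors' own. Each deposited table has 1 row without a gene name, which was left out, and 55289 named genes. Genes with an adjusted p, called tested here, numbered 17619 in the brain-named, 19847 in the heart, 19630 in the kidney, 22211 in the liver-named and 23092 in the spleen table.

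No test per gene was run anew: the authors' adjusted p was used with a false discovery rate of 5%. Depth per library is not in the tables, and its only trace is the set of mean values that genes with a single read take. From these, size factors of the libraries were recovered without a link to sample or genotype, and a spleen value is in doubt. The precision of each value is the authors' standard error, with a median over genes of mean 20 or more of 0.45, 0.49, 0.64, 0.55 and 0.64 in the brain-named, heart, kidney, liver-named and spleen tables. How many single libraries share a direction cannot be counted from these tables.

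For groups of genes, 53 lists of pathways, complexes and markers of cell types were fixed before the data were examined. Each was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic over tested genes, 2-sided, with a preset inter-gene correlation of 0.01 and at least 5 tested members, adjusted by Benjamini and Hochberg over 265 tests. A correlation estimated from the data needs values per library, so a preset value of 0.05 was the alternative. The p of a list test therefore measures agreement among genes and not among mice. A further 4 lists were written after the data were seen and appear in the closing part alone, adjusted among themselves where a p is given. Members passing were counted over all genes and adjusted over the list alone. Differences between 2 tables were tested by a z from the standard errors for up to 10 genes that passed in 2 tables and Ftsj1, and by the same camera test on that z for lists that passed in 2 tables in opposite directions, so both were selected on the values tested. These tests treat tables as independent, although 4 organs share mice. Overlaps and classes of genes were compared by Fisher's exact test, 2-sided. Classes of genes came from RefSeq names, without coordinates, for 91.5% to 95.2% of tested genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

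Genes named in the comparisons were chosen by a rule, also fixed then, with the exceptions given here. It took Ftsj1, the 10 largest rises and 10 largest falls per table among genes past the threshold with a mean of at least 20, up to 4 members past the threshold per list or, in a list that passed with none, 3 others, and up to 10 genes past it in 2 tables. Gene models without a descriptive symbol were counted by the rule and mostly left unnamed, and not every gene of the rule is printed. Foxp1, Aadat and Mdga2 fall outside it and were named after their values were seen, to complete the 9 shared falls. Alb and Cpe were named as the highest means of their tables, and Clps, Rnase1, Prss2, Gp2, Aqp12, Cckar, Bpifa1, Scgb3a1, Mcpt4, Tpsb2, mt-Tl1, mt-Tm and mt-Tn, and in the kidney table Cyp11b1 and Cyp21a1, also after their values were seen.

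The tests were checked on simulated data. With 200 genes changed per table, a log2 change of 2 was found in 66%, 46%, 42%, 38% and 36% of cases in the brain-named, heart, kidney, liver-named and spleen tables, and a log2 change of 1 in 4% in the spleen table. Of 10 shifted lists per table, between 8 and 10 were found. Among unshifted lists, 1 was called in each of the brain-named, kidney and spleen tables and 0 in the other 2. The simulated values were independent across genes, with a spread of 1 for lists and the deposited standard errors taken as exact for genes. The checks therefore cannot show how often lists of correlated genes are called falsely.

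The alternatives were other thresholds of 1% and 10%, adjustment over every gene with a p-value, a mean of at least 20, a log2 change of at least 1, a test statistic rescaled by its robust spread, ranks in the list test, and, for pairs of tables, Pearson's r and higher means. Another normalization, another test, leaving out libraries and blocking by brothers need values per library and were not run.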

Results

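Degradome sequencing reads the 5' ends of uncapped poly(A) RNA, and each value is a number of short tags from such ends. For transcripts made with a cap, these ends come from molecules that lost it or were cleaved. Their values are therefore not the level of the intact transcript. This reading does not extend to mitochondrially encoded transcripts, which are made without a cap. Ftsj1 is an X-linked gene that encodes a tRNA 2'-O-methyltransferase, and the series compares mice deficient in it with wild-type mice. The data hold 32 libraries from 14 male mice aged 4 months. Brain, heart, kidney and liver were taken from the same 6 mice, with 3 deficient and 3 wild-type libraries per organ. Spleen was taken from 8 other mice, with 4 libraries per genotype. The mice belong to 5 sets of brothers. The authors' deposited tables list 55289 named genes per organ, with a mean normalized count over all libraries of that organ. These means summed to 73405489 in the brain-named table, 50435521 in the heart table, 48536401 in the kidney table, 68138128 in the liver-named table and 48733902 in the spleen table. Totals per library are not in the tables, so the depth of each library is unknown. Genes seen by a single read gave size factors of the libraries, which spanned 1.30-fold in the liver-named table and 2.84-fold in the spleen table, the narrowest and widest spans recovered. The spleen value of 0.743 may instead come from genes with more than a single read in the library at 1.486. A spleen library may thus lack its own value, and the spleen span is uncertain.

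Neuron genes were highest in the table named for liver, and genes for secreted hepatocyte proteins in the table named for brain. The median mean count of the 27 neuron genes was 6195 in the liver-named table and 119 in the brain-named table. The median of the 23 genes for secreted hepatocyte proteins was 106291 in the brain-named table and 436 in the liver-named table. Alb, which encodes serum albumin, had the highest mean of the brain-named table, 16371074, or 22.3% of its sum. Cpe, a peptide-processing enzyme of neurons and endocrine cells, had the highest mean of the liver-named table, 443944. Sarcomere genes of cardiomyocytes were highest in the heart table, with a median of 72772, and proximal tubule genes in the kidney table, with a median of 33658. B cell genes were highest in the spleen table, with a median of 4005. That table also held pancreatic acinar transcripts, which made up 21.6% of its sum, against 0.475% in the brain-named table. These 2 tables are called by their deposited names, brain-named and liver-named, throughout.

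**Figure D1:**
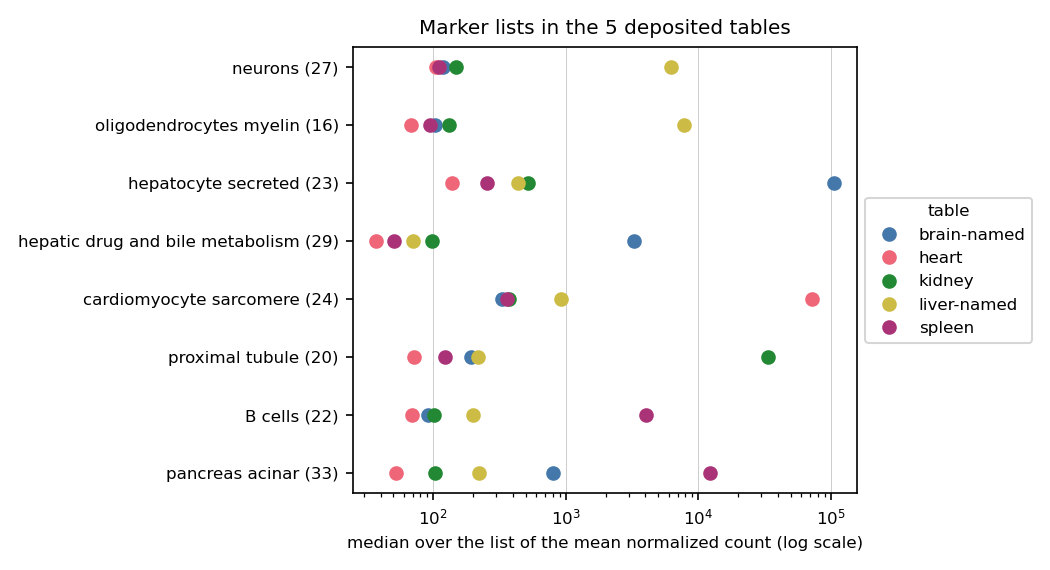
Median over each marker list of the mean normalized count (log scale) in the 5 tables, 1 point per table and list, with the number of list genes in brackets. Neuron genes had a median of 6195 in the liver-named table and secreted hepatocyte proteins a median of 106291 in the brain-named table.

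Tags of Ftsj1 itself, the targeted gene, fell in 3 tables. The authors' deposited tables give log2 fold changes with standard errors of -2.83 ± 0.38 in the brain-named table (adjusted p = 1.75e-09), -3.38 ± 0.59 in the liver-named table (adjusted p = 1.76e-04) and -3.17 ± 0.77 in the spleen table (adjusted p = 0.0261). The values in the authors' deposited heart and kidney tables were -1.72 ± 1.03 (adjusted p = 0.594) and -1.56 ± 0.61 (adjusted p = 0.202), which did not pass. None of the 10 differences between tables passed, with the smallest adjusted p = 0.0894 between kidney and liver-named, by a z test on the 2 standard errors over a family of 102 differences. At an unadjusted p under 0.05, that difference alone was counted. The tables do not state the direction of the fold change, and positive values are read here as higher in deficient mice because Ftsj1 is negative in all 5. After rescaling of the test statistic by its robust spread, the liver-named value had an adjusted p = 0.0561.

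**Figure D2:**
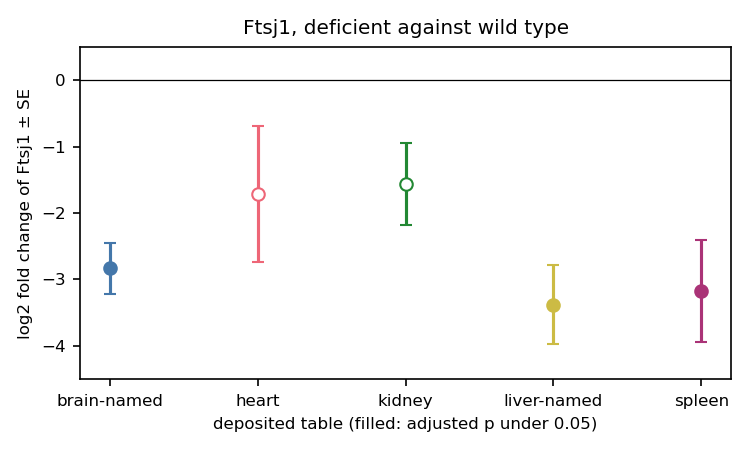
Log2 fold change of Ftsj1, deficient against wild type, in each of the 5 authors' deposited tables, with bars for the standard error given there. Filled points had an adjusted p under 0.05, and all 5 values lie below 0.

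The comparison in the brain-named table, which holds hepatocyte transcripts, asks what differs between deficient and wild-type mice in that tissue. Pancreatic acinar genes, which encode digestive enzymes, rose as a group, with a median log2 fold change of 4.02. All 23 tested members of 33 were positive, a further 4 had counts but no p in the authors' deposited table, 3 rose over all genes tested and 23 rose adjusted over the list alone (list test adjusted p = 5.83e-23). The 3 were Pnliprp1, a lipase relative, Spink1, a trypsin inhibitor, and Amy2a5, an amylase, at 3.11 ± 0.76, 2.97 ± 0.73 and 2.63 ± 0.69 in the authors' deposited table. The list test measures agreement among acinar genes, which may vary together, and not among mice. Whether a single library carried their rise cannot be told without values per library. Genes of fatty acid oxidation and the fasting response also rose, and genes of lipid and cholesterol synthesis fell. Acinar transcripts, at 0.475% of the sum of this table, moved beside each of these groups.

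Of 29 tested genes of fatty acid oxidation, 2 rose over all genes and 10 adjusted over the list alone, with a list median of 0.54 (adjusted p = 1.93e-05). They were Fgf21, a fasting hormone, at 2.26 ± 0.38 (adjusted p = 3.26e-05) and Cyp4a14, a fatty acid hydroxylase, at 1.95 ± 0.35 (adjusted p = 1.23e-04) in the authors' deposited table. Of 19 genes of hepatic lipid synthesis, 1 fell over all genes and 7 adjusted over the list alone, with a median of -0.55 (adjusted p = 5.40e-09). It was Thrsp, a lipogenic gene, at -1.88 ± 0.41 in the authors' deposited table. Of 21 cholesterol synthesis genes, 1 fell over all genes and 3 adjusted over the list alone, with a median of -0.52 (adjusted p = 9.35e-05), and Lss, lanosterol synthase, was at -1.64 ± 0.44 in the authors' deposited table. Cytosolic ribosomal protein genes rose with a median of 0.85 (adjusted p = 4.65e-14), with 1 of 71, Rpl38 at 2.09 ± 0.56 in the authors' deposited table, over all genes and 19 adjusted over the list alone. Nuclear genes of oxidative phosphorylation rose with a median of 0.85 (adjusted p = 2.19e-12), although 0 of 76 passed alone over all genes by the authors' DESeq2 test, with 38 at an unadjusted p under 0.05 and 28 adjusted over the list alone. Mitochondrial ribosomal proteins had a median of 0.50 (adjusted p = 5.49e-06), with 1 of 70 adjusted over the list alone, and the 15 mitochondrially encoded genes a median of 0.84 (adjusted p = 5.49e-06), with 6 adjusted over the list alone. For these groups DESeq2 passed 0 members over all genes, with 16 and 7 at an unadjusted p under 0.05. Macrophage genes rose with a median of 0.68 (adjusted p = 9.35e-05). Of their 21 tested members, 2 rose over all genes, Marco at 2.47 ± 0.66 and Aif1 at 1.81 ± 0.48 in the authors' deposited table, and 4 adjusted over the list alone.

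In all, 73 genes passed at a false discovery rate of 5% in the brain-named table, 59 up and 14 down. Outside the groups above, the authors' deposited table lists Slc22a26, an organic anion transporter, at 3.30 ± 0.65, Snord118, the U8 small nucleolar RNA, at 3.14 ± 0.65, Nupr1, a stress-response gene, at 2.40 ± 0.53 and Fos, an immediate early gene, at 2.28 ± 0.55. Falls in the authors' deposited table included Crhbp at -1.95 ± 0.48, Slc13a2 at -2.16 ± 0.52, Pou2af2 at -2.16 ± 0.49, Bmf at -2.25 ± 0.60, Cyp21a1, steroid 21-hydroxylase, at -2.37 ± 0.48 and Fndc11 at -4.07 ± 1.07. Of the 73, 31 were gene models without a descriptive symbol. A list test with a preset correlation of 0.05 kept 9 of the 14 lists that passed, all those described above. It lost small nucleolar RNA host transcripts (median 0.68, adjusted p = 0.0130, then adjusted p = 0.126 with a preset correlation of 0.05), interferon-stimulated genes (median 0.53, adjusted p = 0.0176, then 0.246), adrenal genes (median -0.45, 0.0332, then 0.0861), secreted hepatocyte proteins (median 0.40, 0.0332, then 0.249) and male-biased liver genes (median -0.06, 0.0439, then 0.338). Of these 5 lists, 2 had a member past the threshold over all genes, Ifi27l2a at 1.41 ± 0.33 in the authors' deposited table and Cyp21a1, and the counts adjusted over the list alone were 0, 1, 1, 1 and 2. In the other 3, DESeq2 passed 0 members, with 6, 3 and 7 at an unadjusted p under 0.05. With the test statistic rescaled by its robust spread, 9 genes passed in place of 73.

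In the heart table, mitochondrially encoded genes fell as a group, with a median log2 fold change of -0.56 (adjusted p = 2.63e-08). Of 15 tested members, 14 were negative, 1 fell over all genes and 6 adjusted over the list alone. It was mt-Nd3, a complex I subunit, at -1.10 ± 0.24 (adjusted p = 0.00175) in the authors' deposited table. Pdk4, a kinase that restrains glucose oxidation, was at 1.83 ± 0.49 and Angptl4, a lipase inhibitor, at 1.22 ± 0.34 in the authors' deposited table, and both rose, while the list of fatty acid oxidation did not pass (median -0.02, adjusted p = 0.761). Sqle, squalene epoxidase of cholesterol synthesis, fell, at -1.98 ± 0.30 (adjusted p = 2.94e-07) in the authors' deposited table. Secreted hepatocyte proteins fell, with 0 of 21 members positive and a median of -0.63 (adjusted p = 5.06e-04). No member passed alone by DESeq2 over all genes, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. These hepatocyte transcripts were low in the heart table, with a median mean count of 138, and the fall was not limited to them. Of genes typical of the brain-named, kidney, spleen and liver-named tables, a class defined after the data were seen as a mean of at least 5000 there and under 3% of it in each other table, 84.2%, 81.2%, 65.6% and 63.5% were negative in the heart table, with median log2 fold changes of -0.54, -0.53, -0.45 and -0.15. Adipose genes fell with a median of -0.71 (adjusted p = 0.00168), with 0 of 15 passing over all genes by DESeq2, 8 at an unadjusted p under 0.05 and 5 adjusted over the list alone.

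In all, 236 genes passed in the heart table, 83 up and 153 down, and 62 of them were gene models. The authors' deposited table puts Fchsd1 at 5.68 ± 1.34, C1qtnf6 at 5.17 ± 1.30, Treml1, a platelet receptor, at 3.47 ± 0.93, Slc7a5, an amino acid transporter, at 1.05 ± 0.28, Rps12, a ribosomal protein, at 1.22 ± 0.32 and Isg15, an interferon-stimulated gene, at 0.85 ± 0.20 among the rises. Among the falls it puts Isy1 at -7.67 ± 2.03, Ctsw at -6.23 ± 1.59, Cyp26a1 at -6.02 ± 1.49, Krt17 at -5.69 ± 1.02, Cd5, a T cell surface protein, at -4.53 ± 0.89, Ighm, an immunoglobulin heavy chain, at -2.28 ± 0.66 and Snhg10 at -2.47 ± 0.68 in the authors' deposited table. The mean of Ighm was 0.684% of its highest table mean and that of Cyp26a1 1.72%. Genes typical of the spleen table stood at a median of 0.626% there. Of the 6 lists that passed, 3 were lost with a preset correlation of 0.05: pancreatic acinar genes (median -0.51, adjusted p = 0.00291, then adjusted p = 0.0741), acute phase genes (median -0.70, adjusted p = 0.0178, then 0.140) and hepatic drug and bile metabolism (median -0.55, adjusted p = 0.0391, then 0.286). For the last 2 of these lists the counts adjusted over the list alone were 0 and 1, and over all genes DESeq2 passed 0 members, with 7 and 1 at an unadjusted p under 0.05. With the test statistic rescaled, 38 genes passed in place of 236.

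In the kidney table, genes of fatty acid oxidation rose and adrenal genes fell. Of 28 tested genes of fatty acid oxidation, 24 were positive, with a median of 0.35 (adjusted p = 9.22e-04, and adjusted p = 0.0489 with a preset correlation of 0.05). The count was 1 over all genes and 2 adjusted over the list alone, and the 1 was Cyp4a14 at 3.15 ± 0.89 in the authors' deposited table. Of 14 adrenal genes, 7 were tested and a further 6 had counts but no p in the authors' deposited table. By default DESeq2 leaves out a p where a library's count is an outlier. How many libraries carried the fall of adrenal genes cannot be told without values per library. All 7 tested were negative, with a median of -2.76 (adjusted p = 0.00511, and adjusted p = 0.0245 with a preset correlation of 0.05). Of these, Star, the cholesterol carrier of steroid synthesis, fell over all genes, at -4.65 ± 1.03 in the authors' deposited table, and 3 fell adjusted over the list alone. Mitochondrially encoded genes had a median of -0.60, with 14 of 15 negative (adjusted p = 0.0176, then adjusted p = 0.126 with a preset correlation of 0.05). DESeq2 passed 0 of its members over all genes, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

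In all, 407 genes passed in the kidney table, 237 up and 170 down, and 120 were gene models. Another 883 genes with a mean of at least 20 had no p there. That number was 34 in the brain-named, 190 in the heart, 301 in the liver-named and 666 in the spleen table. Counts of genes passing are therefore no measure of the size of the genotype effect between tables. Rises in the authors' deposited table included Usp18, an interferon-stimulated protease, at 5.53 ± 0.78 (adjusted p = 3.15e-09), the cell cycle genes Kif11 at 3.07 ± 0.60 and Bub1b at 3.61 ± 0.99, Stc2, a stress-response gene, at 2.28 ± 0.48, Scnn1a, an epithelial sodium channel subunit, at 1.90 ± 0.43, Col6a1, a collagen, at 2.89 ± 0.76 and Serpina3n, an acute phase gene, at 3.52 ± 0.93. Among genes with a mean of at least 20 and a descriptive symbol, the largest rises in the authors' deposited table were Ccl11 at 8.10 ± 2.17, Slc10a3 at 8.03 ± 1.63 and Tcf19 at 7.87 ± 1.87. Falls in the authors' deposited table included Igll1 at -10.04 ± 1.90, Actrt3 at -9.39 ± 1.87, Tmem190 at -8.21 ± 2.33, Adrb3, a receptor of fat cells, at -3.44 ± 0.71, Dbp, a clock output gene, at -3.07 ± 0.65 and Kcnj8 at -1.57 ± 0.43. A fold change as large as that of Igll1, at a mean of 177 over all libraries, places the genotype with the lower value near 0. How many libraries of the other genotype carried the counts cannot be read from such means. With the test statistic rescaled, 139 genes passed in place of 407.

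In the liver-named table, which holds neuronal transcripts, 45 genes passed, 26 up and 19 down, against 55 up and 70 down at a false discovery rate of 10%. Ftsj1 fell. Among the genes with the largest changes, those named below with a descriptive symbol had means from 25.2 for Myl10 to 76.5 for Dsg1b. The gene model Gm28710, also among the largest falls, had a mean of 1589 and was at -5.32 ± 0.99 in the authors' deposited table. Rises in the authors' deposited table were Myl10 at 3.85 ± 0.91, Dsg1b at 3.42 ± 0.75 and Tal2 at 3.38 ± 0.87, and falls Chrne at -4.08 ± 0.89, Oosp3 at -4.76 ± 1.16, Prl5a1 at -4.94 ± 1.05 and the pseudogene Olfr755-ps1 at -9.47 ± 1.68. Pseudogenes made up 16 of the 45, or 35.6%, against 10.2% of the genes tested (Fisher's exact test, 2-sided, adjusted p = 4.52e-05 over 20 tests). By the same test they did not pass in any other table, with the smallest adjusted p = 0.0664 in the brain-named table. Their shares there were 17.8% against 9.3%. In the heart, kidney and spleen tables they were 7.2% against 10.4%, 11.1% against 10.5% and 18.0% against 11.6%. Neuron genes had a median of 0.04 with 13 of 26 positive (adjusted p = 0.761). Interferon-stimulated genes passed as a list, with 24 of 32 positive and a median of 0.40 (adjusted p = 0.0439, then adjusted p = 0.338 with a preset correlation of 0.05). DESeq2 passed 0 of its members over all genes, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Short tags do not tell pseudogenes from their parent genes with certainty. With the test statistic rescaled by its robust spread, 0 genes passed, with 1027 at an unadjusted p under 0.05.

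In the spleen table, 50 genes passed, 28 up and 22 down, against 37 up and 41 down at 10%. Fgf21 fell, at -4.05 ± 1.01 (adjusted p = 0.0350) in the authors' deposited table. Other falls in the authors' deposited table were Foxa2, a transcription factor of endoderm, at -6.19 ± 1.21, Hs3st6 at -6.81 ± 1.15, Prr22 at -6.59 ± 1.26, Prss27 at -5.54 ± 1.41, Zic1 at -5.42 ± 1.32 and Slc52a3 at -4.36 ± 1.10, and H3c8, a histone gene, rose at 6.94 ± 1.43. Neutrophil genes passed as a list with 14 of 18 positive and a median of 1.16 (adjusted p = 0.00559, then adjusted p = 0.0741 with a preset correlation of 0.05). Erythroid genes passed with 22 of 24 positive and a median of 0.65 (adjusted p = 0.0147, then 0.154). Plasma cell genes passed downward with 13 of 14 tested negative, 1 more having counts but no p, and a median of -0.60 (adjusted p = 0.0231, then 0.136). DESeq2 passed 0 members of these 3 lists over all genes, with 3, 0 and 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Beside them, pancreatic acinar genes had a median of -0.34, with 6 of 30 positive (adjusted p = 0.285).

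**Figure D3:**
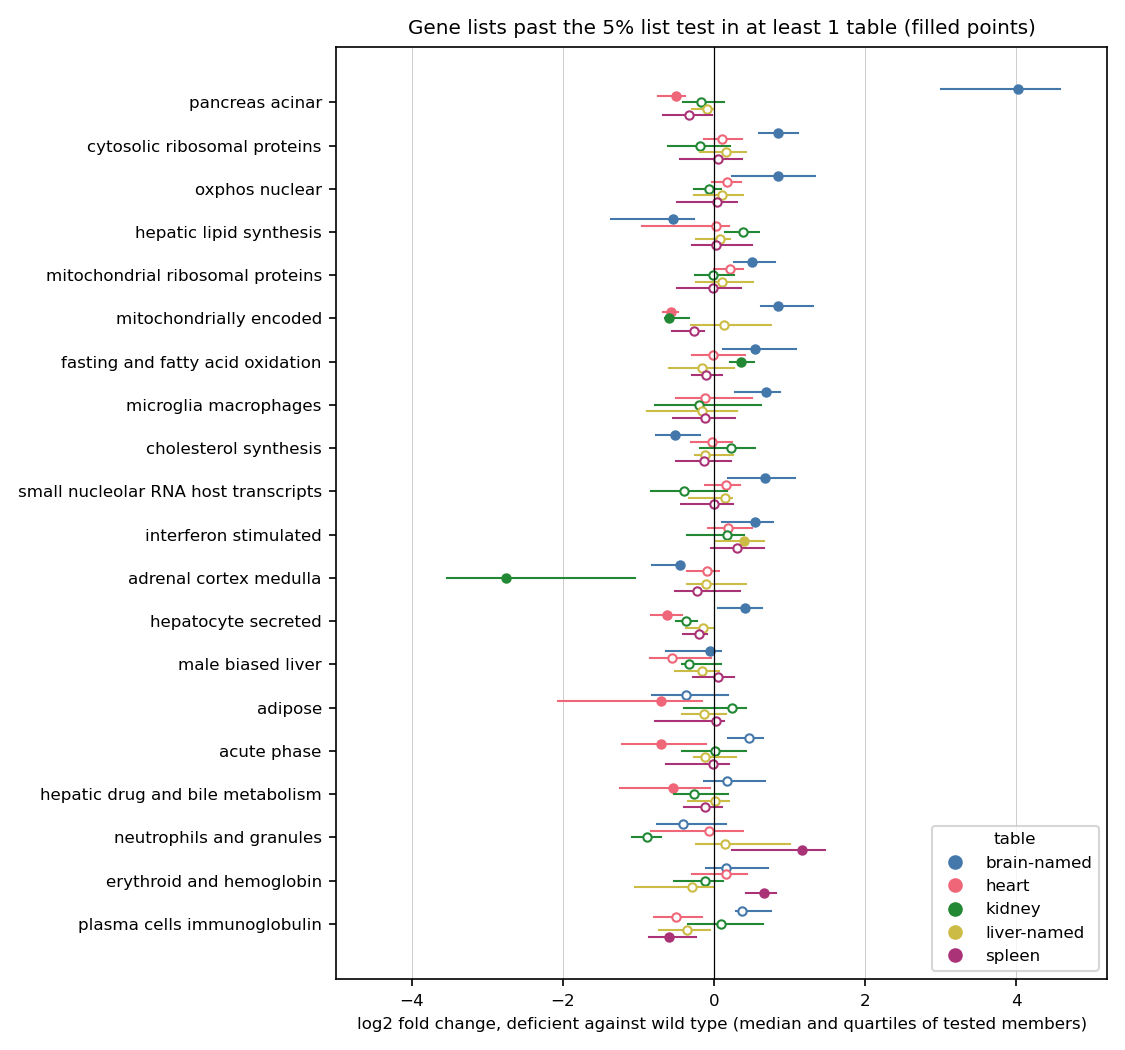
Median log2 fold change, deficient against wild type, with lines from the lower to the upper quartile of tested members, for each list past the 5% list test in at least 1 table, and filled points where it passed. Acinar genes in the brain-named table lie farthest from 0, at a median of 4.02.

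Genes of RNA 2'-O-methylation, a list that includes Ftsj1, did not pass as a list in any table, with the smallest adjusted p = 0.307 in the brain-named table, and Ftsj1 was the 1 member past the threshold in each of the brain-named, liver-named and spleen tables. The median and the mean of that list differed in sign in the heart, liver-named and spleen tables. Genes of tRNA modification did not pass as a list in any table, with medians from 0.04 in the spleen table to 0.26 in the kidney table and the smallest adjusted p = 0.113 in the heart table. In the spleen table the median was positive and the mean and the test negative. Members passed in 2 tables. Trub2, a pseudouridine synthase, rose in the heart table, at 1.87 ± 0.47 in the authors' deposited table. In the kidney table, Tyw3 rose at 2.18 ± 0.64 and Tyw1 fell at -1.25 ± 0.25 in the authors' deposited table, and both act in wybutosine synthesis on tRNA. Factors of decapping and 5' to 3' decay did not pass either, with the smallest adjusted p = 0.493 in the heart table, and DESeq2 passed 0 members in each of the 5 tables, with 4, 2, 1, 1 and 1 at an unadjusted p under 0.05 in the brain-named, heart, kidney, liver-named and spleen tables. Among subunits and partners of the RNA exosome, Exosc5 fell in the heart table, at -1.35 ± 0.38 in the authors' deposited table, and the list had an adjusted p = 0.817 there, with a positive median and a negative mean and test. Among neighbours of Ftsj1 on chromosome X, Magix fell in the heart table, at -1.25 ± 0.32 in the authors' deposited table, and in the kidney table Pim2 rose at 4.20 ± 0.85 and Timm17b fell at -1.64 ± 0.46 in the authors' deposited table. Their list did not pass, with the smallest adjusted p = 0.136 in the liver-named table.

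Between organs, few genes passed in more than 1 table. The number was 16, with 11 in the same direction and 5 in opposite directions. Of the 15601 genes tested in all 5 tables, 14 passed in more than 1, against 5.80 expected from independent lists. Ftsj1 passed in 3 tables. Cyp4a14 rose in the brain-named and kidney tables. Pafah1b2, Efcab6, Scn9a, Septin3, Slc24a4, Foxp1, Gria1, Aadat and Mdga2 fell in both the heart and kidney tables, 9 genes against 0.981 expected (Fisher's exact test, 2-sided, p = 6.18e-07, adjusted p = 2.47e-05 over 40 tests). Scn9a, a sodium channel, was at -1.83 ± 0.39 in the heart and -1.42 ± 0.37 in the kidney in the authors' deposited tables, and Pafah1b2 at -1.55 ± 0.35 and -1.19 ± 0.25. Gria1, a glutamate receptor subunit, was at -1.28 ± 0.35 and -1.36 ± 0.37 in the authors' deposited tables, and Septin3, a septin of neurons, at -1.68 ± 0.35 and -1.24 ± 0.33. The means of Septin3 in the heart and kidney tables were 2.02% and 2.62% of its liver-named mean. Neuron genes did not pass as a list in the heart table, with 20 of 25 negative and a median of -0.14 (adjusted p = 0.119), or in the kidney table, with 20 of 25 negative and a median of -0.42 (adjusted p = 0.0704, with alternatives from 0.0463 on ranks to 0.338 with a preset correlation of 0.05). Across genes, Spearman's rho of the test statistics had a median of 0.0613 over 10 pairs of tables, from -0.0766 for brain-named and kidney to 0.266 for brain-named and liver-named. Genes are not independent replicates, and 4 of the organs came from the same 6 mice.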

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

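All of the tests of explanations in this part were chosen after the results they measure were seen.

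The neuron list had a median mean count of 6195 in the liver-named table and the hepatocyte list 106291 in the brain-named table, signals in tables whose names state another organ. A mixture, in which a share of the brain-named libraries held brain RNA, is argued against: the neuron list's brain-named mean was 0.952% of its liver-named mean, with an upper quartile of 2.61%, and 1 brain library of 6 would give 16.7%. An exchange of the 2 names stays open and is consistent with the values, since the smaller of the 2 lists' folds over the next table was 41.8. Whether table names or sample labels were exchanged was not tested, and no biological explanation was tested.

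Pancreatic acinar genes made up 21.6% of the sum of the spleen table, a signal of an organ no sample is labelled with, and differed by a median of 4.52 log2 units between the brain-named and heart tables, up in the first and down in the other, the fall with an adjusted p = 0.00291 that became 0.0741 with a preset correlation of 0.05. In the heart, kidney and liver-named tables their share of the spleen mean was nearly constant across genes. The robust SD of its log2 was at most 0.324, so reads carried over from spleen libraries may account for them there. Pancreatic tissue in those samples could give such a share too, so this test cannot tell the 2 apart. For the brain-named table carry-over was tested 3 times in turn: the robust SD of 0.854 and the B cell share of 1.99%, with an upper quartile of 6.53%, decided nothing, and the median log2 fold change of B cell genes, -0.011, with an upper quartile of 0.17, argues against it, since spleen RNA would bring both. Pancreatic cells in libraries of deficient mice stay open there, since the outcome turns on which acinar genes outside the fixed list are counted: without Gp2, Aqp12 and Cckar, seen before that list was written, their median log2 fold change was 1.86 over the 8 with a value, 4 of them with a mean under 20, between the bounds of 1 and 2 set for the test, but 3.24 over the 3 tested, which are few, and a first version met the bound at 2.84 with the 3 genes seen before included. An effect of the genotype on acinar transcripts was not tested.

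In the brain-named table, fatty acid oxidation was up and lipid and sterol synthesis down. Dilution of hepatocyte transcripts by pancreatic RNA is argued against by the share of acinar transcripts, 0.475% of the sum of this table, which is too small for such falls. The test set for it was the median log2 fold change of secreted hepatocyte proteins, 0.402 with 18 of 22 positive. At that share this median could hardly respond to dilution, so it decides nothing. A metabolic state of the deficient mice shared by their organs cannot be told apart from other causes: the fatty acid oxidation list rose in the kidney table, but had an adjusted p = 0.761 in the heart table, with 12 of 25 members positive. The bound for that test was revised once, because its first version, a heart median at or below 0, was met by members that go both ways. Genotype itself and food intake before dissection stay open, as untested.

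The other differences given were picked because the gene or list had passed in both tables in opposite directions, so a test of the difference was bound to favour them and adds no support. Fgf21 differed by 6.32 log2 units, brain-named minus spleen. The gene model Gm40787 differed by -13.50, kidney minus spleen. Gpatch3 differed by -10.88 and the pseudogene Cbx3-ps7 by -10.67, heart minus kidney. Mitochondrially encoded genes differed by a median of 1.49 between the brain-named and heart tables and 1.47 between the brain-named and kidney tables, where the kidney fall had an adjusted p = 0.0176 that became 0.126 with a preset correlation of 0.05. Secreted hepatocyte proteins differed by a median of 0.89, brain-named minus heart, and their brain-named rise had an adjusted p = 0.0332 that became 0.249 with that correlation.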

How the results depend on the processing

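The alternatives were fixed before the data were examined, except the removal of genes under 2% of their highest table mean and, for Ftsj1, adjustment over every gene with a p-value, which were chosen after seeing the data. No paired analysis was possible because the deposited tables hold no values per library. For the same reason other size factors, another test per gene, leaving out libraries, blocks by brother set, pseudocounts, estimated correlations and other splits of the samples were not run.

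At 1%, 14 genes passed in the brain-named, 90 in the heart, 184 in the kidney, 8 in the liver-named and 21 in the spleen table, and 4 in at least 2 tables. At 10%, 155 passed in the brain-named, 381 in the heart, 125 in the liver-named and 78 in the spleen table, and 44 in at least 2 tables. A changed threshold moves such counts by its own construction. The balance of direction turned in 2 tables: from 26 up and 19 down, the liver-named table went to 3 up and 5 down at 1% and to 55 up and 70 down at 10%, and the spleen table from 28 up and 22 down to 37 up and 41 down at 10%. Adjustment over every gene with a p-value left 38 in the brain-named table. With the test statistic rescaled by its robust spread, 9 passed in the brain-named, 38 in the heart, 139 in the kidney and 0 in the liver-named table by the rescaled Wald test, the last with 1027 at an unadjusted p under 0.05. Ftsj1 in the liver-named table then had an adjusted p = 0.0561, and its adjusted p over every gene was 2.75e-04. The spread of the statistic was above 1 in those 4 tables, from 1.14 to 1.24, and the cause was not tested.

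With a preset correlation of 0.05, 9 lists passed in the brain-named, 3 in the heart, 0 in the liver-named and 0 in the spleen table by cameraPR. On ranks, 10 passed in the heart, 7 in the kidney and 6 in the spleen table, and the cause was not tested. The other 43 values of these results stayed on the same side of the threshold, within 1.5 times the count or, for the correlation between tables, within its spread over pairs. Of the lists that passed under any of these settings, 0 reversed direction. Depth per library is unknown, and the simulated log2 change of 1 was found in 4% to 22% of cases, so small changes were mostly not detectable.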

Other observations

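The tests in this part were chosen after the data were seen. The list of mitochondrial tRNAs was written after the values of its members in all 5 tables had been seen, so a test of it would restate them and no p is given for it. In heart, 19 of 21 tested members were negative, with a median log2 fold change of -1.15, and 5 fell over all genes. Among the 22 in the liver-named table, 21 were negative, with a median of -1.49, and in kidney, 16 of 19 were, with a median of -0.90. Of 18 tested in the brain-named table, 17 were positive, with a median of 0.93. The spleen table had a median of -0.18, with 11 of 16 negative. In the authors' deposited heart table, mt-Tl1 was at -1.23 ± 0.29 (adjusted p = 0.00581) and mt-Tm at -1.40 ± 0.37 (adjusted p = 0.0220), and in the authors' deposited kidney table mt-Tn was at -1.79 ± 0.37 (adjusted p = 4.70e-04).

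Of the acinar genes outside the fixed list, 9 were tested in the spleen table and all 9 were negative, with a median of -0.997 (adjusted p = 0.00162, and adjusted p = 0.00731 with a preset correlation of 0.05). The list of acinar genes fixed in advance did not pass there, with 24 of 30 tested members negative and a median of -0.34 (adjusted p = 0.285, and adjusted p = 0.683 with that correlation). The 9 include Gp2 and Cckar, whose brain-named values had been seen before that list was written, and not Aqp12, which has no p in the authors' deposited spleen table. In the kidney table, the authors' deposited table gives no p for the adrenal genes Cyp11b1 and Cyp21a1, whose log2 fold changes were -9.14 ± 3.41 and -9.24 ± 1.98. In the heart table, the mast cell proteases Mcpt4 and Tpsb2 fell, at -5.01 ± 0.76 (adjusted p = 2.59e-07) and -4.90 ± 1.01 (adjusted p = 0.00128) in the authors' deposited table, and of the 8 tested members of a list of mast cell genes, written after these 2 were seen, 4 were positive. The airway genes Bpifa1 and Scgb3a1 had log2 fold changes of -7.76 ± 2.73 and -4.12 ± 1.62 in the authors' deposited heart table, without a p. Of the 15 airway genes, 2 were tested there, so that list was not tested in the heart.

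Genes typical of another table, with a mean of at least 5000 there and under 3% of it in each other table, were listed at a median of at most 1.39% of that mean. They numbered 134 for the brain-named, 40 for the heart, 49 for the kidney, 235 for the liver-named and 34 for the spleen table. In the brain-named table their median log2 fold changes were 0.37, 0.44, 0.03 and 0.65 for genes typical of the heart, kidney, liver-named and spleen tables, and 6 of the 34 typical of spleen belong to the acinar list. In the kidney table the medians were -0.39, -0.52, -0.42 and -0.65 for genes typical of the brain-named, heart, liver-named and spleen tables. For the liver-named table they were -0.12, -0.16, -0.16 and -0.06, typical of brain-named, heart, kidney and spleen, and for the spleen table -0.17, -0.08, -0.58 and 0.04, typical of brain-named, heart, kidney and liver-named. Of the genes past the threshold, 4 in the brain-named, 14 in the heart and 4 in the kidney table had a mean under 2% of their highest table mean, and 0 in the other 2. They include Pnliprp1, Spink1 and Amy2a5 in the brain-named, Cyp26a1 and Ighm in the heart and Serpina3n in the kidney table.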
